A study of Homo sapiens with 6 samples.

How the data were processed

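Small RNA from MCF7 mammospheres was made into libraries with the QIAseq miRNA Library Kit, per the labels' protocols, for 3 untreated samples and 3 samples given 2 µM withaferin A over 5 days. The submitters' processing notes name Trim Galore, cutadapt, edgeR and the genome GRCh38.p7, without versions or roles. The locus caller and the counter are not given in the sources used here. That kit adds molecular identifiers, and no source says whether the counts are of reads or of identifiers, so intervals and floors cover counting error only.

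The authors deposited a table of whole-number counts per hairpin locus for the 6 libraries, which was used for the main tests. A second table deposited by the authors holds a normalised score, the counts multiplied by 1 factor per library and rounded. Those factors differed by at most 0.01% from the mean over the effective library size, computed here with TMM over all 823 rows. Rows carry a running identifier and, for 341 of them, a miRNA name. The identifier is not a coordinate. Of 306 names with an arm 299 are 5p. Among rows with 100 or more counts, 11 differently named pairs with equal counts share their longest stretch of sequence on the hairpin's 3' side. Pairs of miR-320b and miR-320d among them have no arm in their names and do not bear on the arm. Names were therefore read as hairpin loci and not as arms. In 243 rows the counts equal those of another row in every library, and 81 of these rows have 100 or more counts over all libraries. At these 81 reads matching several loci were probably counted at each, whereas rows with few counts may be equal by coincidence. Such loci, and loci of near-identical family members, are uncertain as separate measurements. Of the 341 named rows, 307 were placed by miRNA symbol and chromosome in GENCODE 29 (GRCh38), from which positions, host genes and GC content were taken.

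Loci were kept with filterByExpr by group (409 of 823, holding 99.6% to 99.9% of each library's counts) and scaled with TMM. They were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on group alone, with Benjamini-Hochberg adjustment over all tested loci, a threshold of 0.05 and no fold minimum. CPM values are TMM-normalised and given as mean ± SD of 3 libraries. Because the factor of untreated replicate 1 was 0.418, CPM of very abundant loci are not shares, and shares were taken from the counts. Fixed lists (19, of which 13 had at least 3 tested members) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation (lowest adjusted p 0.389) and fry stand beside it. A list took 1 locus per miRNA, the one with the highest total. Measures of library composition were compared with two-sided exact permutation tests. A floor of 3 counts over the group was used for loci without a count in a group, with 95% exact intervals elsewhere. The lists were let-7, miR-200 with miR-205, miR-183, miR-17-92, p53, miR-15/16, miR-30, miR-29, breast cancer growth, oestrogen receptor targeting, NF-kB, stress, the chromosome 14 and 19 clusters, blood, stroma, other tissues, RNA fragments and Microprocessor-independent miRNAs.

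Loci were named by a rule with 3 parts. The first took the 10 largest rises and the 10 largest falls among called loci with a mean of at least 10 CPM and no overlap between groups. The second took the 5 most abundant loci, and the third up to 4 members per list with the smallest p. Few unnamed loci are printed, since their identifiers pair with no gene. The miR-17, miR-125b, miR-200b, miR-200c, miR-376c, miR-381, miR-409, miR-505, miR-760 and miR-766 loci fell outside the rule and were named after their values were seen. The groups, tests, lists, rule and first set of alternatives were fixed before the data were examined. The composition measures fixed then were total counts, loci with a count, and the shares of the most abundant and the 10 most abundant loci. Those on named loci, the miR-21 locus and the largest unnamed locus were not among them.

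No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 9.87 to 438 over rows with at least 20 counts). On counts simulated from these libraries, the edgeR test called 78.3% of 4-fold and 19.8% of 2-fold changes among 388 loci, and 2.2% of its calls were unchanged loci. Camera called the shifted list and none without a shifted member. The simulation drew loci independently at a common dispersion, without the deviations that loci of a real library share. Its error rates may therefore not hold for the real libraries. Alternatives covered other scalings, filters, the replicate number as a block, each library left out, the miR-21 locus left out, the deposited normalised table with limma and 3 pseudocounts, DESeq2 1.42.0, limma-voom, other thresholds and other list tests. Those added later were scaling by the named loci, named loci alone, 1 row per set of shared reads, and both the deepest and the shallowest library left out. All 6 libraries entered every main test.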

Results

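Small RNA was sequenced from mammospheres, the spheres that MCF7 cells, an oestrogen receptor-positive human breast cancer line, form in serum-free medium on plates to which they cannot attach. Withaferin A, a steroidal lactone from the plant Withania somnifera, was present at 2 µM during the 5 days of sphere culture in 3 libraries and absent in 3 others. The aim given with the series was to find known and newly predicted miRNAs whose expression differed under the compound. The count table held 823 hairpin loci, 341 with a miRNA name and 482 without. Total counts were 1524152, 518103 and 861780 in the untreated libraries and 417084, 445157 and 130716 in the treated ones. The miR-21 locus held 1113198, 271729 and 501635 of these counts in untreated and 27796, 29628 and 3070 in treated libraries. Outside that locus, treated replicates 1 and 2 had more counts than untreated replicate 2, and treated replicate 3 had the fewest. Nothing states that the replicates were separate cultures, so p-values measure only the spread between these libraries.

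The locus of miR-21, a miRNA often described as oncogenic, held most of the counts of untreated mammospheres and few of those of treated ones. Its share was 61.2% ± 10.6 in untreated and 5.22% ± 2.49 in treated libraries (SD, n = 3 each). The untreated libraries had shares of 73.0%, 52.4% and 58.2%, with exact Clopper-Pearson 95% intervals of 73.0% to 73.1%, 52.3% to 52.6% and 58.1% to 58.3%. The treated libraries had shares of 6.66%, 6.66% and 2.35%, with intervals of 6.59% to 6.74%, 6.58% to 6.73% and 2.27% to 2.43%. Against the other loci the miR-21 locus fell by 4.66 on the log2 scale (SE 0.83, 25.3-fold, edgeR quasi-likelihood adjusted p = 0.000752). The weakest estimate over 5 other scalings was a log2 change of -3.51. MIR21 lies at chromosome 17, 59841266 to 59841337 on the plus strand of GRCh38, within an exon of VMP1 in GENCODE 29.

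**Figure D1:**
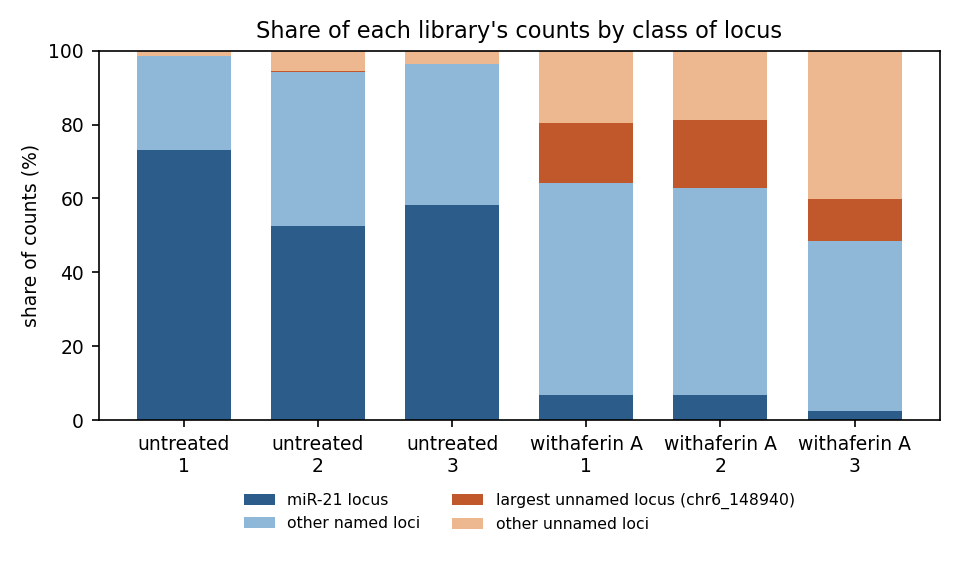
Stacked bars give the percentage of each library's counts (y axis) held by the miR-21 locus, the other named loci, the largest unnamed locus and the other unnamed loci, for 3 untreated and 3 withaferin A libraries (x axis). The miR-21 locus holds 52.4% to 73.0% in untreated and 2.35% to 6.66% in treated libraries.

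The loci with a miRNA name held 96.5% ± 2.13 of the counts in untreated and 58.5% ± 8.60 in treated mammospheres (SD, n = 3 each). The largest unnamed locus, chr6_148940, rose from 0.0763% ± 0.0216 to 15.3% ± 3.71 of the counts and was the most abundant locus of every treated library (log2 fold change 6.70, SE 0.58, edgeR adjusted p = 1.23e-05). Leaving the miR-21 counts aside, the named share was still 91.4% ± 3.35 against 56.3% ± 7.82. Fewer named loci had a count in the treated libraries, 256 ± 25.7 against 314 ± 2.52 (SD, n = 3 each). Treated replicates 1 and 2, with 275 and 267, had fewer such loci than untreated replicate 2, with 314, despite more counts outside the miR-21 locus. In each of the 9 measures of library composition the treated libraries lay all on the same side of the untreated ones, with p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 can give (0.1 after adjustment over the 9).

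Of 409 loci with enough counts to test, 133 were higher and 111 lower under withaferin A (edgeR, adjusted p under 0.05), and 243 of these 244 loci had no overlap between the groups. Separation without overlap was seen at 66.7% of the tested loci, where chance gives 10%. Named and unnamed loci moved apart: 9 of 199 named loci were higher and 102 lower (median log2 change -1.28), whereas 124 of 210 unnamed loci were higher and 9 lower (median 2.38). With loci that shared identical counts or a miRNA name taken once, the numbers were 8 higher and 81 lower among 159 named loci, and 96 higher and 9 lower among 170 unnamed loci. The split depended on the loci that set the scale. Scaling by library totals gave 163 higher and 53 lower loci, of which 24 and 46 were named, and TMM factors from the named loci gave 197 higher and 52 lower, of which 42 and 45 were named. The median log2 change of all tested loci was 0.28 under TMM over all loci, 1.20 under library totals and 1.46 under the factors from the named loci. When the named loci alone were scaled and tested, 46 of 203 were higher and 49 lower (median -0.13). The directions of named loci given below are therefore relative to all tested loci, and the result with the named loci alone scaled and tested is given beside them. Among the loci named below, the calls of miR-30b, miR-30c, miR-30d, miR-34a, miR-141, miR-146b, miR-193b, miR-210, miR-222, miR-375, miR-486, miR-497 and miR-9 ended both with named loci alone and with library totals. The calls of miR-19a and miR-221 ended with library totals, and those of miR-19a and miR-429 with the factors from the named loci. With upper-quartile scaling the calls of miR-30c, miR-141, miR-146b, miR-375, miR-486 and miR-497 ended, and with RLE factors those of miR-30c and miR-141. Leaving out the miR-21 locus ended the same calls as upper-quartile scaling. Without a filter on low counts the calls of miR-30c and miR-375 ended, with limma-voom those of miR-141 and miR-486, and with limma on the deposited normalised table at a pseudocount of 0.5 those of miR-486 and miR-497. Without untreated replicate 1 and withaferin A replicate 3, the deepest and the shallowest library, 24 named loci were higher and 110 lower, and 130 unnamed loci were higher and 27 lower, while the calls of miR-141 (log2 change -0.48) and miR-497 (-0.93) ended. Across the 199 named loci, of which 95% had a GC content and which are not independent replicates, the deviation from the group mean correlated with GC content at a Spearman rho of -0.53 in untreated replicate 1 and 0.47 in withaferin A replicate 3, against 0.44 in both other untreated libraries and -0.40 and -0.43 in the other treated ones. Without untreated replicate 3 the number of higher named loci was 5, and without untreated replicate 1 the number of lower unnamed loci was 16.

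**Figure D2:**
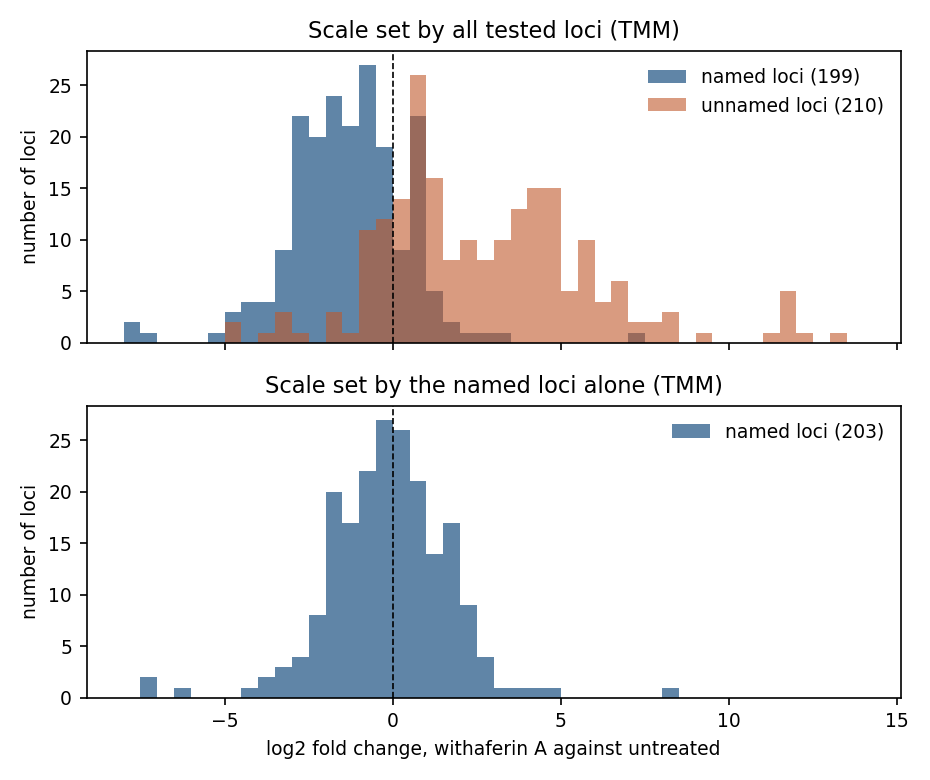
Histograms give the number of loci (y axis) by log2 fold change of withaferin A against untreated mammospheres (x axis), above for 199 named and 210 unnamed loci on the scale of all tested loci, below for 203 named loci on a scale set by themselves. The dashed line marks no change. The median of the named loci is -1.28 above and -0.13 below, and that of the unnamed loci above is 2.38.

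The largest falls at named loci were at miR-549a, miR-1247, miR-31, miR-671, miR-21, miR-219a and miR-10a. The miR-1247 locus went from 485 ± 286 to 5.01 ± 7.10 TMM-normalised CPM (log2 fold change -7.09, SE 1.03, edgeR adjusted p = 0.000191). Its log2 change was -8.92 without treated replicate 3 and -6.32 without treated replicate 2. MIR1247 lies at chromosome 14, 101560287 to 101560422, minus strand, in an exon of DIO3OS. The miR-31 locus (chromosome 9, 21512115 to 21512185, minus strand, in an intron of MIR31HG) went from 219 ± 8.97 to 5.02 ± 8.70 CPM, with 8 counts in treated replicate 1 and none in the other treated libraries. The log2 fold change of miR-31 was -5.18 (SE 0.89) and was -4.54 without treated replicate 2. Without treated replicate 1 it was -9.90, but no treated count was left there, so that value does not measure the size of the fall. The miR-671 locus, in an exon of CHPF2 on chromosome 7 (151238421 to 151238538, plus strand), fell by 4.66 on the log2 scale (SE 0.48, edgeR adjusted p = 3.76e-05). The miR-10a locus, in the HOXB region of chromosome 17, fell by 4.19 (SE 0.70). Both loci named miR-549a had no count in treated mammospheres, at least 21.6-fold and 20.4-fold lower against a floor of 3 counts over the group. Their untreated counts were nearly the same, 44, 18 and 29 against 43, 18 and 25, so they are probably not separate measurements. The miR-219a locus held 111 counts in untreated and 3 in treated libraries, a ratio of 26.3 with a counting interval of 8.78 to 130, and its log2 change of -4.59 was -5.44 without treated replicate 1. These falls passed the test under each other scaling in which the locus was tested.

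The 10 largest rises were all at unnamed loci, 7 of them without a count in any untreated library. The locus chr19_362717 had 2425 counts in treated libraries and none in untreated ones, at least 1140-fold higher against the same floor. Of these 10 loci, 4 held identical counts in every library. Among unnamed loci that fell, chr5_120525 went from 101 ± 23.3 to 2.43 ± 2.11 CPM and chr19_363545 from 286 ± 42.3 to 9.87 ± 5.73 CPM (SD, n = 3). The table gives neither coordinates nor an RNA class for unnamed loci.

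The let-7 family, whose members are widely described as tumour suppressors that restrain RAS and HMGA2, had members that rose. Of 7 tested, 3 were higher, 2 when adjusted over the list alone, and none was lower (median log2 change 0.93). The let-7c locus rose from 5951 ± 444 to 17210 ± 1731 CPM (log2 fold change 1.53, SE 0.34, edgeR adjusted p = 0.0027). MIRLET7C lies at chromosome 21, 16539828 to 16539911, plus strand, in an intron of MIR99AHG. The let-7i locus rose from 8494 ± 2830 to 23820 ± 6840 CPM (1.49, SE 0.42) and the let-7a locus from 15080 ± 2988 to 33290 ± 12060 CPM (1.14, SE 0.42). The let-7a call ended with a filter on a mean of 10 CPM, with limma on the deposited normalised table, and without untreated replicates 1, 2 or 3 or treated replicates 1 or 2, and the let-7i call without untreated replicates 2 or 3 or treated replicates 1 or 2. The leave-one-out log2 changes were 0.89 to 1.24 for let-7a and 1.22 to 1.60 for let-7i. With named loci alone all 7 members were higher (median 2.09). The set test against the other loci did not pass (camera adjusted p = 0.353). With named loci alone it did (camera adjusted p = 0.000481), a call lost with an estimated correlation (adjusted p = 0.373).

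All 3 members of the miR-29 family, known regulators of collagen and DNA methyltransferase transcripts, fell on every scaling tried. The miR-29a locus went from 21960 ± 4300 to 2014 ± 924 CPM (log2 fold change -3.44, SE 0.48, edgeR adjusted p = 0.000169). It lies at chromosome 7, 130876747 to 130876810, minus strand, in an intron of a lincRNA. The log2 fold changes of miR-29b and miR-29c were -2.75 (SE 0.52) and -3.04 (SE 0.58). The list did not pass as a set (camera adjusted p = 0.0604; 0.0116 to 0.389 over the alternatives). It passed with library totals (0.0253), upper-quartile scaling (0.0471), no filter (0.0425) and directional fry (0.0165), and without untreated replicate 2 (0.0349) or 3 (0.0449). It also passed with factors from the named loci, where unnamed loci were still tested beside it (0.0116). Settings in which it did not pass included an estimated correlation (adjusted p = 0.389) and named loci alone (0.0821). Others were without untreated replicate 1 (0.0997) or treated replicates 1 (0.0516), 2 (0.0706) or 3 (0.0724). Of 5 miR-30 members 4 were lower, with miR-30e at -2.63 (SE 0.52) and miR-30d at -1.90 (SE 0.35). Of these, 1 was lower with named loci alone, miR-30e. The miR-30c call ended without untreated replicate 1 or treated replicate 2 (log2 change -0.86 at its weakest), and the log2 change of miR-30b went from -2.29 to -1.53 without untreated replicate 1.

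Among miRNAs of epithelial identity, 4 of 6 were lower. The miR-205 locus went from 1581 ± 87.0 to 167 ± 38.1 CPM (log2 fold change -3.25, SE 0.39, edgeR adjusted p = 8.56e-05) and lies at chromosome 1, 209432133 to 209432242, plus strand, in an exon of MIR205HG. The miR-200a and miR-429 loci, neighbours on chromosome 1, fell by 2.66 (SE 0.56) and 2.46 (SE 0.65). Without untreated replicate 1 the log2 change of miR-429 was -1.78. The miR-141 locus fell by 1.62 (SE 0.62), a call that ended in limma fits of the deposited normalised table, with loci that share reads taken once, and without untreated replicate 1 or treated replicates 2 or 3, with log2 changes of -2.04 to -1.01 over the 6 libraries left out. The miR-200b and miR-200c loci did not pass, at log2 changes of -0.58 and 0.09. With named loci alone 3 members were lower and 1, miR-200c, was higher, and the log2 change of miR-200b was 0.60. In the miR-183 cluster miR-96 fell by 3.18 (SE 0.69, edgeR adjusted p = 0.0022), while miR-183 (-0.17, SE 0.37) and miR-182 (0.04, SE 0.40) did not pass. Without untreated replicate 1 the log2 change of miR-96 was -2.38. The miR-183 and miR-182 loci were higher and the miR-96 locus lower with named loci alone.

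**Figure D3:**
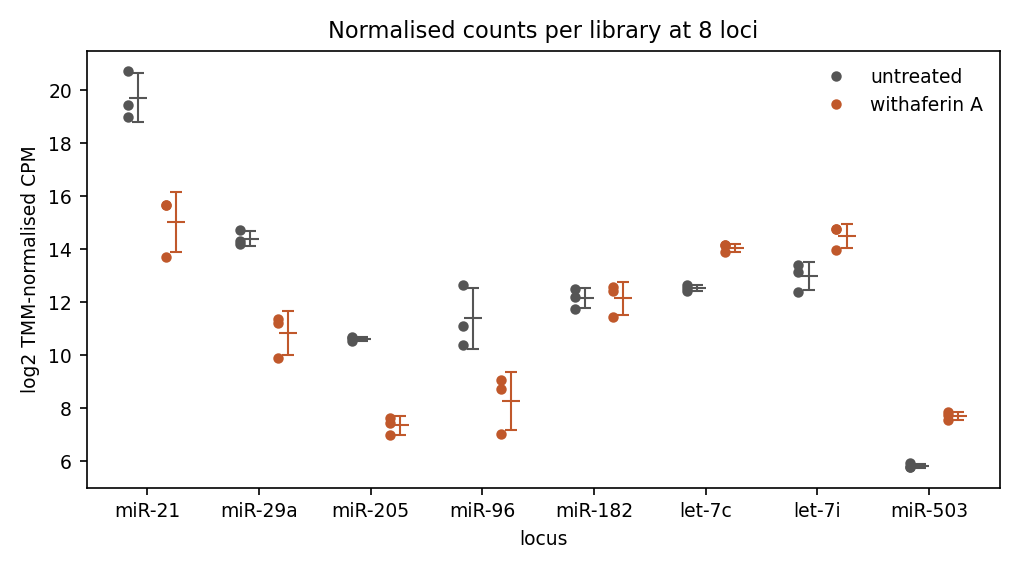
Points give log2 TMM-normalised CPM (y axis) of each library at 8 loci (x axis), grey for untreated and orange for withaferin A, with the mean and SD of the 3 libraries beside them. miR-21, miR-29a, miR-205 and miR-96 lie lower and let-7c, let-7i and miR-503 higher in the treated libraries. miR-182, at a log2 change of 0.04, did not pass the test on this scale and was higher with named loci alone.

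Of 9 tested members of the miR-17-92 cluster and its paralogues, which promote proliferation in many tumours, 6 were lower. They included miR-92a (-2.74, SE 0.43), miR-20a (-2.41, SE 0.44), miR-19a (-3.04, SE 0.79) and miR-19b (-2.60, SE 0.67). The last 2 were at -2.10 and -1.85 without untreated replicate 1. The miR-17 locus was not called (0.69, SE 0.50). It was called higher without untreated replicate 1 (1.23), without the deepest and the shallowest library, with library totals, and with named loci alone (1.98), where 4 members were lower. In the miR-15/16 family of 7, miR-503 rose from 57.1 ± 3.15 to 212 ± 22.2 CPM (log2 fold change 1.88, SE 0.42, edgeR adjusted p = 0.00283) and miR-497 was lower (-1.54, SE 0.56). The miR-497 call did not pass when adjusted over the list alone and ended without untreated replicate 1 or treated replicate 2. The miR-16 loci, among the 5 most abundant, were at 23220 ± 8442 and 37930 ± 10310 CPM and did not pass (0.71, SE 0.43). They were called higher with library totals, with upper-quartile scaling, without the miR-21 locus, without the deepest and the shallowest library, and with named loci alone, where miR-503 was higher too and miR-497 was not called.

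Of the miRNAs described as promoting breast cancer growth or spread, all 6 tested were lower, with miR-221 at -2.27 (SE 0.46), miR-222 at -2.34 (SE 0.52) and miR-210, a hypoxia-induced miRNA, at -2.05 (SE 0.39) beside miR-21. This was the single list of 13 to pass (camera adjusted p = 0.0219). The call was lost with an estimated correlation (adjusted p = 0.389), without treated replicate 3 (0.0724), without the deepest and the shallowest library (0.076) and without the miR-21 locus (0.0585), and its adjusted p ranged from 0.00203 to 0.389 over all alternatives. The list had 2 lower members with named loci alone, miR-21 and miR-221, and did not pass (0.0593). The other 12 lists had camera adjusted p values of 0.0604 to 0.771. Without untreated replicate 2, and likewise without untreated replicate 3, the number of lists passing was 6, namely this list and those of miR-29, miR-30, miR-17-92, epithelial identity and NF-kB. All list members are named loci, whereas the loci they were set against include 210 unnamed ones (median log2 change 2.38). These set tests therefore carry the split of named and unnamed loci. With named loci alone the camera adjusted p was 0.0821 for miR-29, 0.582 for miR-30 and epithelial identity, 0.677 for miR-17-92 and 0.334 for NF-kB. Of 5 miRNAs with NF-kB-dependent expression 4 were lower, among them miR-132 (-2.80, SE 0.50) and miR-146b (-1.50, SE 0.52), the latter not without untreated replicate 3 or treated replicate 1. The miR-125b locus, the member not called (-0.10, SE 0.34), was higher with named loci alone, where miR-21 and miR-132 were lower. Of 7 miRNAs described as targeting the oestrogen receptor, 4 were lower, including miR-22 (-2.37, SE 0.49) and miR-193b (-2.15, SE 0.54), and 2 were higher, let-7a and let-7i. With named loci alone the same members were higher and 2, miR-22 and miR-221, were lower. Of 4 p53-dependent miRNAs 1 was lower, miR-34a (-1.34, SE 0.38), a call that ended without untreated replicate 3. Of 5 hypoxia and redox stress miRNAs 3 were lower, namely miR-210, miR-34a and miR-141. None was lower with named loci alone, where miR-200c was higher. These lists overlap: miR-21 and miR-9 stand in both the growth and the NF-kB list, and miR-221 and miR-222 in both the growth and the oestrogen receptor list. Adjusted over the list alone, the numbers of calls were the same in the lists other than let-7 and miR-15/16.

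Among 4 miRNAs made without the Microprocessor complex, miR-484 fell from 900 ± 396 to 50.5 ± 5.59 CPM (log2 fold change -4.16, SE 0.51), whereas the miR-320b, miR-320c and miR-320d loci, which hold identical counts, did not pass (0.62, SE 0.44) and were higher with named loci alone. The median log2 change of this list was 0.62, its mean was -0.57, and camera placed it lower (adjusted p = 0.771). Of 2 tested entries that resemble fragments of other RNAs, miR-1260b fell (-3.86, SE 0.65, and -4.62 without treated replicate 3) and miR-4492 did not pass (1.11, SE 0.71, and 0.32 to 1.45 over the libraries left out), though it was higher with named loci alone. The blood marker miR-486 was lower (-1.94, SE 0.65), a call lost without untreated replicates 2 or 3 or treated replicates 1 or 2. The stromal miR-199a and miR-199b loci, which share their counts, did not pass (0.19, SE 0.61). Of the miRNAs listed for liver, neurons, neuroendocrine and pluripotent cells 2 were tested. The miR-375 locus was lower (-1.16, SE 0.37), though not without untreated replicate 3 or treated replicates 1 or 2, and its log2 change was 0.09 with named loci alone. The miR-7 locus, at 3462 ± 1860 and 5018 ± 2252 CPM, did not pass (0.54, SE 0.50). It was higher with library totals, without the deepest and the shallowest library, and with named loci alone. Of 23 miRNAs of the imprinted chromosome 14 cluster in the table, 1 had enough counts to test, miR-432. It was higher at a low level (3.94 ± 2.23 against 22.1 ± 6.78 CPM), a call that ended without untreated replicate 3, and does not stand for the cluster. Without the miR-21 locus 3 other members were tested and miR-432 was not, and all 3, miR-376c, miR-381 and miR-409, were lower. A mixed result came without the deepest and the shallowest library, with 1 higher and 1 lower of 3 tested members (median log2 change -0.23, camera adjusted p = 0.9). Without a filter on low counts the list was lower as a set (camera adjusted p = 0.0174, and 0.0174 to 0.9 over the alternatives in which it could be tested). None of the miRNAs listed for the chromosome 19 cluster stood in the table.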

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

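The last 4 settings, scaling by the named loci, named loci alone, 1 locus per set of shared reads, and leaving out the deepest and the shallowest library, were chosen after seeing the data. The 244 called loci became 191 to 317 over the settings in which unnamed loci were tested (172 to 183 in 10 draws with every library thinned to 130716 counts), and no shared call changed direction in any setting. At least 185 of the 244 were shared in each setting where all loci were tested. The smallest, 185 and 186, came from scaling by the named loci and by library totals. With named loci alone, 110 of the main calls were tested and 58 were shared. The gap between the median log2 changes of named and unnamed loci was -3.96 to -2.52 over these settings (main -3.66) and -4.85 on average after thinning. Without each library in turn, the fall in the miR-21 share ranged from -60.4 to -50.1 percentage points (main -56.0) and that of the named share from -40.8 to -33.0 (main -38.0).

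The 9 higher named loci became 24 with library totals, 16 with upper-quartile scaling, 15 without the miR-21 locus, 42 with scaling by the named loci, 46 with named loci alone and 24 without the deepest and shallowest library (5 to 11 without each library). The 102 lower named loci became 46, 45 and 49 with library totals, scaling by the named loci and named loci alone. These scalings place zero elsewhere between the 2 classes. The 9 lower unnamed loci became 24 without a filter, where more loci were tested, 14 without the miR-21 locus and 27 without the deepest and shallowest library (7 to 16 without each library); the cause was not tested for the last 2.

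The single list passing became 3 with library totals, 4 with upper-quartile scaling, 5 without a filter, 3 with a minimum mean of 10 CPM, 3 with scaling by the named loci, 8 with directional and 10 with mixed fry, and 0 with an estimated correlation, without the miR-21 locus and without the deepest and shallowest library (0 to 6 without each library). With named loci alone the 1 list passing was let-7. The lists added beside that of breast cancer growth were miR-29 and NF-kB with library totals and with scaling by the named loci, these and miR-17-92 with upper-quartile scaling, these 3 and the chromosome 14 cluster, which was lower, without a filter, and miR-17-92 and NF-kB with a minimum mean of 10 CPM. The cause was not tested, except that fry does not compare a list with other loci.

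With the replicate number as a block, 240 loci and 0 lists were called, 233 of the loci shared with the main calls; the breast cancer growth list, the 1 passing otherwise, had an adjusted p of 0.0668 with it (0.00203 to 0.389 over all alternatives). Whether the numbers pair the samples is not stated and stays open. Deviations of same-numbered libraries correlated at 0.65, -0.35 and 0.41. Untreated replicates 1 and 3 correlated best with their own number, whereas untreated replicate 2 did so with treated replicate 3 (0.57). Deviations from a mean of 3 sum to 0, so these correlations cannot decide it. The miR-182 log2 change was -0.01 with the block, and the let-7a call ended with it.

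Of 1919 alternative values at 81 loci, 1711 kept direction and side of the threshold, 108 lost the call, 39 gained it and 61 changed sign. Of the loci that changed sign, miR-375 was called in the main test and the others were not; the cause was not tested. Under library totals they were miR-183 0.80, miR-107 0.53, miR-192 0.76, miR-194 0.72, miR-15a 0.12, miR-28 0.05, miR-125b (a pair of loci) 0.86 and miR-200b 0.49. Upper-quartile scaling gave miR-183 0.20, miR-125b 0.29, miR-192 0.03 and miR-194 0.09, and leaving out the miR-21 locus gave miR-183 0.16, miR-125b 0.24 and miR-194 0.02; with RLE factors miR-125b was at 0.00. Scaling by the named loci, then named loci alone, gave miR-183 0.98 and 0.99, miR-107 0.70 and 0.72, miR-192 0.84 and 0.85, miR-194 0.82 and 0.85, miR-15a 0.16 and 0.19, miR-28 0.24 and 0.26, miR-125b 1.14 and 1.15, miR-375 0.08 and 0.09, and miR-200b 0.58 and 0.60. Without the deepest and shallowest library they were miR-183 0.23, miR-107 0.01, miR-192 0.29, miR-194 0.47, miR-15a 0.11, miR-200b 0.27 and miR-200c -0.10. Without each library in turn the ranges were -0.28 to 0.14 for miR-182, -0.73 to 0.03 for miR-192, -0.60 to 0.09 for miR-194, -0.36 to 0.75 for miR-199a and miR-199b, and -0.18 to 0.24 for miR-200c. Depth limits treated replicate 3 most, where 3 counts correspond to 13.1 CPM, against 5.65 and 5.27 in the other treated libraries and 4.28 to 5.69 in untreated ones.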

Other observations

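The test of miR-21 against a common shift, the share under library totals and the ratios within clusters were chosen after the results were seen.

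Of the 9 named loci that rose, 4 were of the let-7 family, with let-7a at a pair of loci that share reads, and 2 were miR-503 and miR-432. The other 3, named after their values were seen, lay near or below the floor of 4.28 to 5.69 CPM in untreated libraries. The miR-505 locus, in an intron of ATP11C, was at 4.79 ± 2.88 CPM in untreated and 54.0 ± 6.00 in treated mammospheres (log2 fold change 3.42, SE 0.62, edgeR adjusted p = 0.00076). The miR-760 locus was at 5.47 ± 2.23 and 46.8 ± 28.1 CPM (2.99, SE 0.66; 2.30 without treated replicate 3). The miR-766 locus, in an intron of SEPT6, had no count in the untreated libraries and 39.4 ± 19.8 CPM in the treated ones. Ratios within each library, which do not depend on the scale, are given for 4 pairs of cluster neighbours picked because their log2 changes differed, so that they do not test whether neighbours differ in general. Other members of 1 cluster had like changes, such as miR-19a (-3.04) and miR-19b (-2.60). The ratio of miR-20a to miR-17 counts, 460 bases apart on chromosome 13, was 7.84, 14.9 and 12.5 in untreated and 1.40, 1.45 and 0.708 in treated libraries. That of miR-96 to miR-183, 213 bases apart, was 1.49, 0.478 and 0.647 against 0.121, 0.143 and 0.0625. That of miR-200a to miR-200b was 6.82, 5.61 and 8.04 against 1.71, 1.68 and 1.27. Each of these 3 had an exact permutation p of 0.1, the smallest that 3 against 3 allow. The miR-141 to miR-200c ratio overlapped between the groups (exact permutation p = 0.3). Which arm gave these counts is not known.

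The first pattern is the parting of named and unnamed loci. After every library was thinned to 130716 counts the gap was 132.6% of its size before (mean of 10 draws), so that it remained at equal totals. At equal totals the miR-21 locus kept most of the untreated counts, so the treated libraries had the greater depth at the other loci. A lower depth of the treated libraries was reversed there, yet the gap did not shrink. Without each library in turn, treated replicate 3 included, the gap was -3.96 to -3.17. These values argue against lower depth as the source of the gap. After thinning this covers the 272 to 282 loci tested, against 409 before. Fragments of multi-copy RNAs at the unnamed loci remain possible. Of the rising unnamed loci 34.7% shared their counts with another locus, against 22.1% of the other tested unnamed ones (Fisher's exact p = 0.0645). Loci with identical counts entered that test separately though they are not independent, so its p-value cannot decide the question. Which class changed in absolute amount cannot be told apart: with named loci alone scaled and tested 51.6% of called named loci were lower, but that scale centres them and so fixes the share near its value, and scaled by library totals it was 65.7%. A response of the cells to the compound, loss of miRNAs or gain of other small RNAs, stays open and untested, as no external standard sets the scale.

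The second pattern is the fall of the miR-21 locus. It does not rest on a single library, since the weakest log2 change without each in turn was -4.08. Nor does the fall against other loci rest on the choice among the scalings tried, since the weakest of 5 others gave -3.51. All were computed from these same counts, so they do not bear on the absolute amount of miR-21. A shift common to all named loci is argued against by the same -3.51, found with the named loci alone scaled and tested, which takes such a shift out. The treatment itself stays open as a hypothesis that was not tested further.

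The third pattern is that untreated replicate 1 and withaferin A replicate 3 departed from their groups in opposite ways, with a correlation of -0.69 across loci, which are not independent replicates. The correlation kept 101.4% of its size after thinning to equal totals. Library depth is not decided by this, since depth at the loci other than miR-21 was not made equal. GC content of the hairpins may be part of the cause: over 95% of the 199 named loci the deviation correlated with GC at a Spearman rho of -0.53 in the first library and 0.47 in the second. The other libraries had rho of 0.44 and 0.44 (untreated) and -0.40 and -0.43 (treated), in part because deviations from a mean of 3 sum to 0, so that the trend does not mark these libraries alone. No biological explanation was tested for this pattern.

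With edgeR the real grouping called 244 loci and the highest of the other 9 groupings of 3 against 3 called 0 (at most 14 at an unadjusted p under 0.05, against 256), with 1 of the 10 splits reaching the real number. For lists 7 of the 10 splits called as many as the real grouping, which called 1, and the highest other called 7. The 10 splits are too few for a share under 0.05. Each of the other 9 also set treated and untreated libraries together on both sides. The treatment difference then widened the spread within their groups, which left little room for locus calls. The splits with 6 or 7 lists joined untreated replicate 1 and another untreated library to withaferin A replicate 1 or 2. They keep part of the treatment contrast and so cannot show a structure of the samples beside it.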
